A study of Mus musculus with 16 samples.

How the data were processed

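Gene expression was measured in sorted mouse skin epithelial cells on 16 one-colour Agilent arrays, 1 array for each of 16 groups. Per the labels' protocols, hair follicle stem cells (HFSC) were sorted as CD34-high, ITGA6-high and Sca1-negative cells and interfollicular epidermal cells (IFE) as ITGA6-high and Sca1-high cells, and amplified cDNA was labelled with Cy3. Per the file headers, spots were quantified with Agilent Feature Extraction 11.5.1.1 on an array of 62976 features whose design uses the mm9 build. For each array the authors deposited the scanner output, in which the processed signal is an intensity on a linear scale, background-subtracted and detrended within the array per the file headers and not scaled between arrays. A deposited value table for the same arrays holds log2 values; set against the scanner files it equals log2 of the processed signal minus the 75th percentile of the array, to within rounding. The labels do not say whether the arrays come from separate animals or whether cells of several mice were pooled.

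Control spots and spots that the scanner software marked as outliers were left out, log2 of the processed signal was taken, the 75th percentile of each array was subtracted, and spots of a probe were averaged. Of 55681 probes, the 49835 that were well above background on at least 2 of the 16 arrays were kept. Each gene was represented by its probe with the highest mean over the 16 arrays, which gave 31545 gene rows, 17806 of them with an official symbol. Probes were named through accessions in a RefSeq gene table (28026 probes), through a current symbol (3418) or through a synonym (295), and the other 23942 kept the name in the file. The scanner file of the young control tHFSC array ends early and holds 46417 of the 55681 probes. The 9264 missing probes were filled from the value table, without background flags, and an alternative used only probes held in all 16 scanner files. No spot was saturated.

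The arrays lie on 2 slides, each with its own scan. Slide 1 holds the 8 young HFSC arrays and slide 2 holds the 4 aged HFSC and 4 IFE arrays. The age comparison in HFSC therefore cannot be told apart from the slide. The comparisons between cell states, between the knockouts and their control, and between arrays of the IFE lie within slides. On both slides the tHFSC arrays occupy columns 1 and 3 and the aHFSC arrays columns 2 and 4.

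Because each group has 1 array, conditions were tested in 1 limma fit of all 16 arrays (lmFit and eBayes with a mean-variance trend, two-sided, Benjamini-Hochberg adjustment over all genes, threshold 0.05). The fit has a term for each of the 6 HFSC conditions, a common aHFSC-minus-tHFSC shift, and an intercept, an age term and a transgene term for IFE, which leaves 6 residual degrees of freedom. A further fit adds a state-by-age term and has 5. The spread in these tests is the scatter of cell states and of age and genotype combinations around the additive fit, so p-values measure that scatter and not the variation between animals. The limited number of arrays limits the precision.

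The 11 comparisons, the rule for named genes, 20 lists of gene programs and 10 lists of markers of other cell types were fixed before the data were examined. Named genes have an official symbol and are the 8 highest and 8 lowest log2 differences past the threshold with the same sign in every pair of arrays, up to 4 members of a fixed list (those past the threshold first, then by unadjusted p), and, where fewer than 3 genes pass, the 3 highest and 3 lowest with the smallest unadjusted p, stated as not passing. Col17a1, Prkci, Prkcz and the sort genes Cd34, Itga6 and Ly6a are always included. Statements on the smallest p-values are therefore among genes with an official symbol. Genes outside the rule are stated as such where they appear. Lists were tested with limma's camera with a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over 330 tests. With the preset value 61 of the 330 tests passed, and with the estimated correlation 1 did, the bulge list in tHFSC against IFE. Log2 differences are given with their standard error (SE). Where a probe was not well above background on any array of a group, the fold is a lower bound: the mean of the brighter group against the higher, per array, of the lowest signal among probes well above background and the dim probe's own signal. The bounds hold for the processing described here, and under the alternatives below some fitted differences were smaller than them. Where a probe was well above background on only some arrays of a group, the fitted difference is partly measured against background.

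Alternatives were normexp background correction (offset 50), quantile normalization, no filter on dim probes, only probes well above background on all 16 arrays, the mean of a gene's probes, only the arrays of a comparison, unpaired groups, eBayes without a trend, slide as a block or fits within a slide, the deposited value table, and leaving out each array in turn. Quantile normalization moved the median log2 difference over all genes by 0.19 for the age by transgene interaction, by 0.10 for the transgene in HFSC and by -0.12 for the transgene in IFE, and normexp moved it by 0.16 for age in HFSC, by 0.14 for the transgene in HFSC and by 0.17 for the interaction; all other shifts were under 0.1. Correlations between effects that share control arrays were set beside the value from 20 simulations of unchanged arrays over the 31074 genes with values on all arrays.

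The fits were tested on simulated data in which known changes were added to some of the 31074 genes. A log2 change of 4 was recovered in 100% of changed genes for aHFSC against tHFSC, 79.1% for tHFSC against IFE, 63.9% for the Col17a1 knockout, 74.0% for the aPKC knockout, 62.7% for their difference, 90.5% for age in HFSC, 95.5% for the transgene in HFSC, 31.3% for the age by transgene interaction, 55.6% for age in IFE, 74.2% for the transgene in IFE and 40.6% for the difference in state shift between ages. For a log2 change of 2 the shares were 66.1%, 56.1%, 13.7%, 28.1%, 13.8%, 52.6%, 43.0%, 1.59%, 12.7%, 13.9% and 5.88% in the same order, and for a change of 1 none exceeded 8.33%. Analyses ran in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.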

Results

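The series follows how hair follicle stem cells divide during regeneration and aging. HFSC were profiled in 6 conditions, each as an array labelled tHFSC and an array labelled aHFSC. The labels do not spell out these abbreviations, and they give hair plucking 3 days before collection for the aHFSC of control and Col17a1 knockout mice. The conditions were young control, young Col17a1 conditional knockout (cKO), young aPKC cKO, young hCOL17A1 transgenic, aged wild-type (WT) and aged hCOL17A1 transgenic mice. COL17A1 is the transmembrane collagen of the hemidesmosomes that anchor basal keratinocytes, and aPKC here is the lambda isoform of atypical protein kinase C, a cell polarity kinase encoded by Prkci. IFE was profiled in 4 groups, young and aged, WT and hCOL17A1. Young mice were 12 weeks and aged mice 25 to 26 months old. Control and knockout mice received 2.5 mg of RU486 over 5 days from 8 weeks of age, and the other labels do not mention it, so young control mice differ from aged WT and from hCOL17A1 mice in that treatment too. Between 74.0% and 80.0% of probes were well above background on 14 arrays, against 69.1% for aged hCOL17A1 tHFSC and 59.6% for aged hCOL17A1 aHFSC. The young hCOL17A1 IFE array correlated less with the other IFE arrays (r from 0.919 to 0.925 across genes) than those did with each other (0.975 to 0.979). No group has a replicate array.

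The targeted genes were examined first. Col17a1 signals, as log2 minus the 75th percentile of the array, were 7.02 in control tHFSC and 6.17 in control aHFSC, and 6.75 and 5.97 in the Col17a1 cKO. Over the other 12 arrays they ran from 5.85 to 7.52. The fitted cKO difference was -0.23 ± 0.21 (SE, adjusted p = 1). Its probe lies on mm9 chromosome 19, 47720894 to 47720953, and the labels do not say which part of the gene was deleted, so a probe outside that part checks nothing. Prkci signals were 4.25 and 4.37 in control tHFSC and aHFSC and 3.44 and 3.28 in the aPKC cKO, the lowest of the 16 arrays. The difference of -0.95 ± 0.30 had the same sign in 2 of 2 pairs but did not pass (adjusted p = 1; probe on mm9 chromosome 3, 30951503 to 30951562, with the same limit). Prkcz, the other atypical isoform, differed by -0.43 ± 0.94 in the aPKC cKO (adjusted p = 1).

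aHFSC were compared with tHFSC within each condition to find what the change of state brings. Genes of DNA replication and mitosis rose: of 40 measured cell cycle list members, 39 had a positive difference, 14 passed over all genes and 30 adjusted over the list alone. Among them were Uhrf1, which maintains DNA methylation at replication forks (log2 difference 2.36 ± 0.25), the helicase subunits Mcm6 (1.61 ± 0.17) and Mcm4 (1.22 ± 0.15), the ribonucleotide reductase subunit Rrm2 (1.52 ± 0.20) and cyclin A2, Ccna2 (3.69 ± 0.48). Each was higher in 6 of 6 conditions, with an adjusted p from 0.0333 to 0.0338. Their calls were lost in 10, 11, 11 and 16 of 26 alternatives in that order, and for Ccna2 in 12 of 25. The list median was 1.84, from 0.90 in the aPKC cKO to 2.65 in aged WT (camera adjusted p = 4.14e-34, adjusted p = 0.176 with an estimated correlation). It was 1.64 within slide 1 and 1.86 within slide 2. The largest rises were those of S100a9, an alarmin of stressed keratinocytes and myeloid cells (5.28 ± 0.74), the gap junction gene Gjb2 (4.85 ± 0.83), the proteoglycan gene Bgn (4.49 ± 0.50), the thyroid hormone deiodinase Dio2 (4.25 ± 0.63), the cohesion factor Dscc1 (4.02 ± 0.57), the kinetochore gene Zwilch (3.60 ± 0.34) and the transcription factor Sox4 (3.40 ± 0.54). Dscc1 was well above background on 1 of 6 tHFSC arrays and S100a9 on 2 of 6, so these 2 differences are partly measured against background. Calls were lost in 16 of 25 alternatives for S100a9, 17 of 25 for Gjb2 and for Dscc1, and 11 of 26 for Bgn. For Dio2 it was 17 of 26, for Zwilch 9 of 26 and for Sox4 18 of 26.

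**Figure D1:**
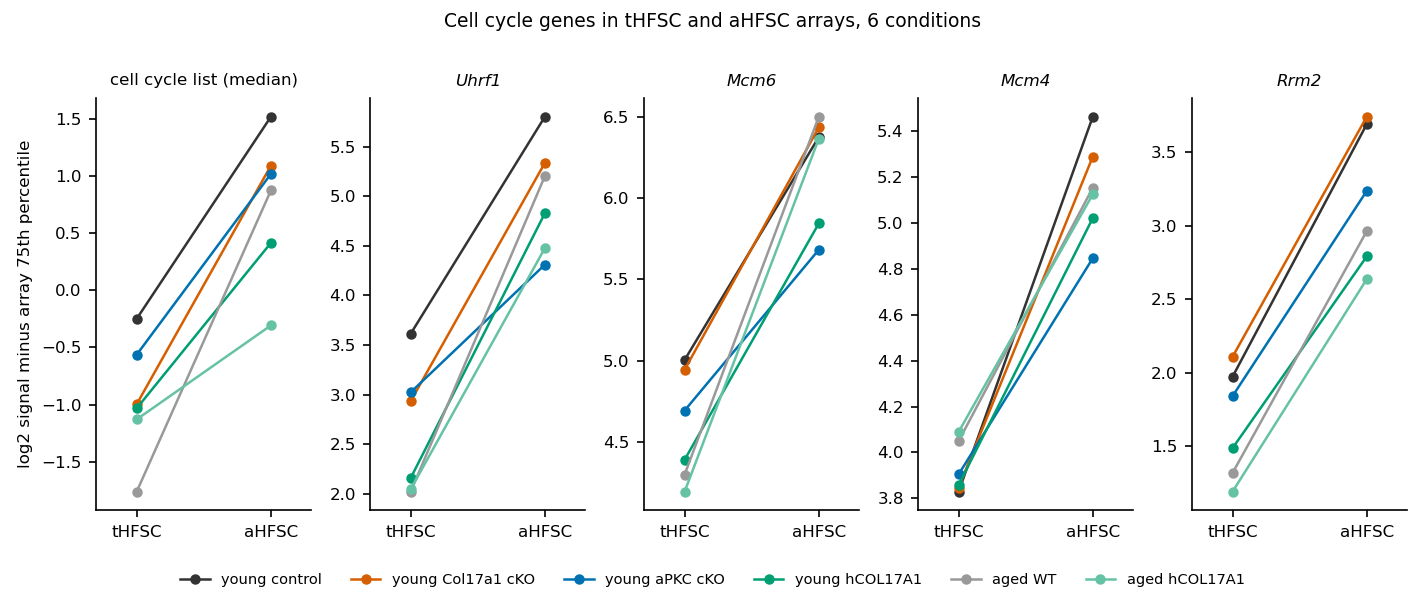
Log2 signal minus the 75th percentile of the array (y axis, its own range in each panel) in tHFSC and aHFSC (x axis), for the median of the cell cycle list and for 4 of its members. Each line joins the 2 arrays of 1 condition, with no replicate arrays, and all 6 lines rise in every panel shown.

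Genes that fell in aHFSC included Phyhipl (-4.29 ± 0.58), Hid1 (-3.92 ± 0.64), the Wnt pathway antagonist Dact1 (-3.84 ± 0.49), the synaptic organiser C1ql3 (-3.59 ± 0.54), Cyp26b1, which degrades retinoic acid (-3.50 ± 0.31, adjusted p = 0.0303), and Zfp354b (-3.31 ± 0.45). Of these, Phyhipl and Zfp354b were well above background on 2 of 6 aHFSC arrays, and Hid1, Dact1 and C1ql3 on 3 of 6. Over the alternatives the differences weakened to -1.53 for Phyhipl, -1.375 for Hid1 and -0.67 for Dact1, but only to -3.15 for Cyp26b1. The calls were lost in 15 of 25, 20 of 24, 20 of 25 and 9 of 26 alternatives in that order. Glt8d2 and Hspa12a were not well above background on any aHFSC array and were at least 4.43-fold and 4.89-fold lower there. Over the alternatives their fitted log2 differences weakened to -0.76 and -0.77, smaller than these bounds. Their calls were lost in 20 and 16 of 25 alternatives. Col17a1 itself fell (-0.81 ± 0.12, adjusted p = 0.0363, lower in 6 of 6 conditions), a call lost in 18 of 26 alternatives. Col17a1 was the single member of 21 in the hemidesmosome and basement membrane list to pass. In the BMP and TGF-beta list 15 of 20 members were lower (median -0.73, adjusted p = 0.00309, adjusted p = 0.301 with an estimated correlation). There the BMP target Id2 fell (-1.68 ± 0.25), a call lost in 17 of 26 alternatives. Single members of other lists also passed: the Wnt target Tcf7 (1.36 ± 0.23), the stress gene Gadd45a (2.51 ± 0.37) and the serine synthesis enzyme Psat1 (2.02 ± 0.28) were higher and the collagen gene Col1a2 (-2.20 ± 0.24) was lower. Their calls were lost in 21, 15, 15 and 10 of 26 alternatives in that order. The wound and stress keratinocyte list had 12 of 19 members higher (median 0.83, adjusted p = 0.00111, adjusted p = 0.264 with an estimated correlation), among them S100a9, but its median was 0.34 with normexp and -0.12 within slide 2. Oxidative phosphorylation genes shifted by a median of 0.40 (23 of 26 positive, adjusted p = 9.5e-07, or adjusted p = 0.644 with an estimated correlation) and ribosomal protein genes by 0.25 (22 of 24, adjusted p = 2.23e-06, or adjusted p = 0.684; 0.14 with quantile normalization), where the median of all genes was -0.09. Adjusted over the list alone, 5 wound and stress genes and 2 oxidative phosphorylation genes were higher, and 7 BMP and TGF-beta genes lower. Of the sort genes, Cd34 was lower in 6 of 6 conditions (-1.70 ± 0.81, adjusted p = 0.44), as was Ly6a (-1.41 ± 0.36, adjusted p = 0.148). Itga6 differed by 0.03 ± 0.12. The Cd34 error, here and in the comparisons below, pools all 16 arrays. The 6 Cd34 pairs ran from -2.72 to -0.73, but the transgene differences between IFE arrays were -1.21 and 6.77. Its errors and p-values therefore largely measure the scatter of the IFE arrays. Prkcz was lower in 6 of 6 without passing (-2.73 ± 0.54, adjusted p = 0.0785), and Prkci differed by -0.24 ± 0.17 (adjusted p = 0.616).

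In all, limma called 170 genes in aHFSC against tHFSC, 121 higher and 49 lower, each with the same sign in 6 of 6 conditions. The count was 0 within slide 1, 0 within slide 2 and 0 without either aged WT array. It was 1 without the Col17a1 cKO tHFSC array or either young hCOL17A1 array, 2 without either control array, 3 without the Col17a1 cKO aHFSC array. It was 81 without either aged hCOL17A1 array and 95 without either aPKC cKO array. Without the 2 arrays that stand apart, aged hCOL17A1 aHFSC and young hCOL17A1 IFE, it was 111.

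Sorted follicle and epidermal populations were compared as tHFSC against IFE of the same ages and genotypes, 4 arrays each. Young control tHFSC, labelled with RU486, stood against young WT IFE, whose label does not mention it. Bulge stem cell genes separated the populations: 15 of 21 list members rose in tHFSC over all genes tested and 19 adjusted over the list alone, with a median of 4.39 (adjusted p = 3.6e-29, and adjusted p = 0.0105 with an estimated correlation). The transcription factors Lhx2 (7.47 ± 0.17), Sox9 (4.67 ± 0.17) and Tbx1 (9.18 ± 0.39), the stem cell receptor gene Lgr5 (8.57 ± 0.65) and the sort gene Cd34 (9.72 ± 0.96, adjusted p = 0.000988) were higher in 4 of 4 pairs, with Cd34 well above background on 2 of 4 IFE arrays and Lgr5 on 1 of 4. The Wnt inhibitor gene Wif1 was not well above background on any IFE array and was at least 15.8-fold higher. The largest other differences were those of the endocytic adaptor Dab2 (at least 649-fold, adjusted p = 1.1e-05), Pdzrn4 (at least 208-fold), Angptl7 (at least 280-fold), the BMP antagonist Grem1 (9.19 ± 0.69) and the collagen gene Col8a2 (8.16 ± 0.38). Over the alternatives the fitted log2 differences fell to 5.37 for Dab2, 5.06 for Pdzrn4 and 5.14 for Angptl7, smaller than these bounds. BMP and TGF-beta list members moved up on balance (15 of 20, median 1.55, 0.80 with normexp, adjusted p = 1.72e-05, or adjusted p = 0.176 with an estimated correlation): Ltbp1 (5.17 ± 0.38), Ccn2 (7.04 ± 0.60) and follistatin, Fst (3.38 ± 0.30), rose, while Bmp4 fell (-4.55 ± 0.48).

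**Figure D2:**
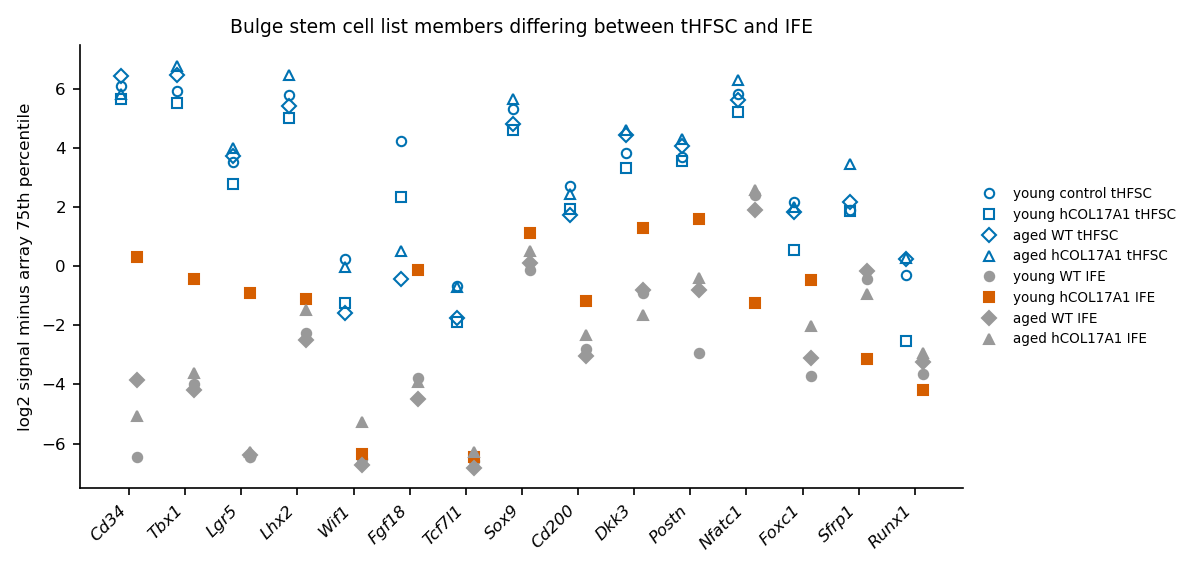
Log2 signal minus the 75th percentile of the array (y axis) for the 15 bulge stem cell list members called between tHFSC and IFE (x axis). Open symbols are the 4 tHFSC arrays and filled symbols the 4 IFE arrays, 1 array per group; on the young hCOL17A1 IFE array Cd34 stood at 0.32, between the other IFE arrays (-6.45 to -3.86) and the tHFSC arrays.

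IFE was higher in the interleukin receptors Il1r2 (-7.54 ± 0.58 for tHFSC minus IFE) and Il20ra (-6.09 ± 0.70), in Ppp2r2c (-7.02 ± 0.62), Ly6c1 (-6.66 ± 0.75), Slc24a3 (-5.88 ± 0.60), Ifi202b (-5.71 ± 0.77) and the alarmin Il33 (-5.70 ± 1.17). Il1r2 and Il20ra were well above background on 1 of 4 tHFSC arrays. The potassium channel gene Kcnj16, not well above background on any tHFSC array, was at least 75.2-fold higher in IFE. Over the alternatives its fitted log2 difference reached -3.80, smaller than that bound. The sort gene Ly6a, which encodes Sca1, was lower in tHFSC (-5.62 ± 0.42), as was Itga6 (-0.86 ± 0.14, adjusted p = 0.0113). Epidermal differentiation genes did not move together (median -0.03, adjusted p = 0.895): Krt1 (-5.04 ± 0.55), Dsg1a (-3.21 ± 0.44) and Krtdap (-1.74 ± 0.28) were higher in IFE and Calml3 (4.40 ± 0.35) in tHFSC. Among wound and stress genes Krt6a (5.50 ± 0.62) and Krt17 (2.02 ± 0.23), both keratins of follicle cells too, were higher in tHFSC and Hbegf (-3.83 ± 0.82) in IFE. Hedgehog target Gli1 (5.11 ± 0.48) was higher in tHFSC, and Gata3 (-1.92 ± 0.22), Wnt10b (-1.77 ± 0.20), the Wnt targets Apcdd1 (-2.84 ± 0.30) and Axin2 (-2.04 ± 0.30) and the Notch ligand Dll1 (-3.43 ± 0.48) in IFE. With only probes above background on all 16 arrays another probe stands for Gli1 in tHFSC against IFE (0.53) and for Ly6c1 (-0.94), and neither passed. In the cell polarity and spindle orientation list Patj (1.64 ± 0.30) and Pard6b (-3.0 ± 0.61) passed in opposite directions. Patj lost its call in 9 of 21 alternatives (lowest 0.69) and Pard6b in 10 of 19 (weakest -0.89).

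Lists that were lower in tHFSC than in IFE with the preset correlation all lost that call with an estimated one. Ribosomal protein genes had 23 of 24 members lower (median -0.77, adjusted p = 5.5e-12, or adjusted p = 0.644), oxidative phosphorylation 24 of 26 (-0.67, 5.96e-06, or adjusted p = 0.667). Cell cycle genes were lower for 37 of 40 (-1.20, 2.11e-06, or adjusted p = 0.644) with Mcm6 (-1.38 ± 0.20), Cdt1 (-3.12 ± 0.53) and Pcna (-1.04 ± 0.21). Immediate early genes were lower for 16 of 20 (-1.41, 5e-05, or adjusted p = 0.644) with Fos (-2.52 ± 0.45) and Zfp36 (-2.68 ± 0.53). The p53 and senescence list had 16 of 18 lower (-1.39, adjusted p = 0.000546, or adjusted p = 0.472), among them Sesn2 (-1.78 ± 0.26) and Gadd45a (-2.70 ± 0.43). For the unfolded protein and integrated stress response list it was 14 of 15 (-0.94, adjusted p = 0.00264, or adjusted p = 0.487). Inflammatory secretion had 16 of 19 lower (-1.20, adjusted p = 0.00581, or adjusted p = 0.472), with Mmp3 at least 5.42-fold lower. Interferon and antigen presentation had 16 of 20 lower (-0.78, adjusted p = 0.0221, or adjusted p = 0.644), with Oas1a (-3.06 ± 0.42) and Psmb8 (-2.36 ± 0.33). With quantile normalization the ribosomal protein median was -0.40, oxidative phosphorylation -0.40 and unfolded protein response -0.60. With normexp inflammatory secretion stood at -0.45, interferon and antigen presentation at -0.33, p53 and senescence at -0.80 and cell cycle at -0.80. Of 21 alternatives, 6 lost the call for interferon and antigen presentation, 3 for inflammatory secretion, 2 for p53 and senescence and 1 for oxidative phosphorylation. Adjusted over the list alone, the members lower in tHFSC were 21 ribosomal protein, 12 oxidative phosphorylation, 15 cell cycle, 12 immediate early, 8 p53 and senescence, 7 unfolded protein response, 6 inflammatory secretion and 4 interferon genes. The fibroblast marker list had 5 of 7 higher in tHFSC (0.84, adjusted p = 0.0253, or adjusted p = 0.472), but its median was -0.05 with normexp. Fbln1 (4.99 ± 0.26) and Col1a2 (4.41 ± 0.29) were higher and Thy1 (-4.93 ± 0.83) lower.

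For tHFSC against IFE 2028 genes were called, 666 higher and 1362 lower. Quantile normalization gave 814 higher and 919 lower. With slide as a block 143 genes passed (92 higher, 51 lower) and within slide 2, where 2 tHFSC arrays remain, 83; the bulge list median was 4.49 in both. Leaving out 1 array gave 830 genes without aged WT IFE, 841 without young hCOL17A1 IFE and 944 without young control tHFSC. It gave 1102 without young hCOL17A1 tHFSC and 1167 without aged WT tHFSC, and the other 3 arrays moved it by less than 1.5 times.

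The Col17a1 cKO was compared with control HFSC in both cell states to see what loss of the gene changes. No single gene passed. In the epidermal differentiation list 26 of 28 members were positive (median 0.98, adjusted p = 3.03e-07, or adjusted p = 0.644 with an estimated correlation). Krt1 stood at 1.97 ± 0.82, Asprv1 at 1.45 ± 0.68, Krt10 at 1.15 ± 0.54 and Krtdap at 0.80 ± 0.41. The list median was 1.82 between the tHFSC arrays and -0.05 between the aHFSC arrays, single arrays whose difference was not tested. Without the Col17a1 cKO tHFSC array it was 0.19 (adjusted p = 0.354). The Langerhans and myeloid cell markers moved with it, by 1.89 in tHFSC and 0.17 in aHFSC (median 1.03, adjusted p = 0.00403, or adjusted p = 0.602). With normexp the marker median was 0.60. The antigen-presenting gene H2-Eb1 stood at 2.35 ± 0.69 and Lyz2 at -1.38 ± 0.60. Wound and stress keratinocyte genes were higher by 0.31 in tHFSC and 1.23 in aHFSC (16 of 19 positive, median 0.87, adjusted p = 6.11e-05, or adjusted p = 0.176). The EGF receptor ligands Areg (3.24 ± 0.79) and Hbegf (3.21 ± 1.21), the wound keratin Krt16 (3.23 ± 0.91) and S100a9 (3.61 ± 1.28) had the largest differences, none past the threshold (adjusted p = 1 for each).

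Immediate early genes were positive for 20 of 20 members (median 0.55, adjusted p = 1.96e-06, or adjusted p = 0.644). The call was lost in 1 of 17 alternatives, with medians from 0.18 to 1.13. Fos stood at 1.55 ± 0.67 and Fosb at 1.76 ± 0.80. Smaller list shifts were those of p53 and senescence genes (0.54, adjusted p = 0.00337, or adjusted p = 0.52), unfolded protein response genes (0.36, adjusted p = 0.00527, or adjusted p = 0.56), upper follicle genes (0.39, adjusted p = 0.0219, or adjusted p = 0.644) and cholesterol synthesis genes (0.28, adjusted p = 0.0375, or adjusted p = 0.644). Of 17 alternatives, 3, 2, 5 and 6 lost these calls in that order, and the p53 and senescence median was 0.32 with normexp. The sort gene Ly6a stood at 2.17 ± 0.62 and Ly6d at 1.73 ± 0.64. Bulge stem cell genes were lower in 20 of 21 members by a small amount (median -0.30, against -0.09 for all genes, adjusted p = 0.0355, or adjusted p = 0.56). This call was lost in 9 of 17 alternatives, with medians from -0.59 to -0.11. Wif1 stood at -1.37 ± 0.47 and Sox9 at -0.50 ± 0.24. The bulge list median was -0.56 in tHFSC and -0.03 in aHFSC. In the lists that moved, 0 members passed over all genes and 0 adjusted over the list alone. limma called 0 genes at the adjusted threshold and 1277 of 31545 at an unadjusted p under 0.05, a smaller share than the 0.05 that chance alone gives. Within slide 1 that number was 1649 and without the arrays that stand apart 1701, both larger shares than 0.05. The comparison with chance therefore depends on the arrays that set the spread. Among genes with an official symbol, the smallest p-values belonged to the decoy receptor gene Il22ra2 (4.65 ± 0.65, adjusted p = 0.619), Prorp (1.77 ± 0.26) and Aif1l (3.16 ± 0.49), and to the nucleotide receptor gene P2ry6 (adjusted p = 0.482; at least 8.69-fold lower), Adgrg4 (at least 3.24-fold lower) and the cadherin gene Cdh11 (-2.46 ± 0.49); none passed. Cd34 (-0.48 ± 1.41) and Itga6 (0.03 ± 0.21) did not differ beyond their error. For Cd34 that error largely comes from the IFE arrays, and the 2 pairs stood at -0.61 and -0.35. Without the control aHFSC array 1 gene passed and without the Col17a1 cKO tHFSC array 2 did.

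**Figure D3:**
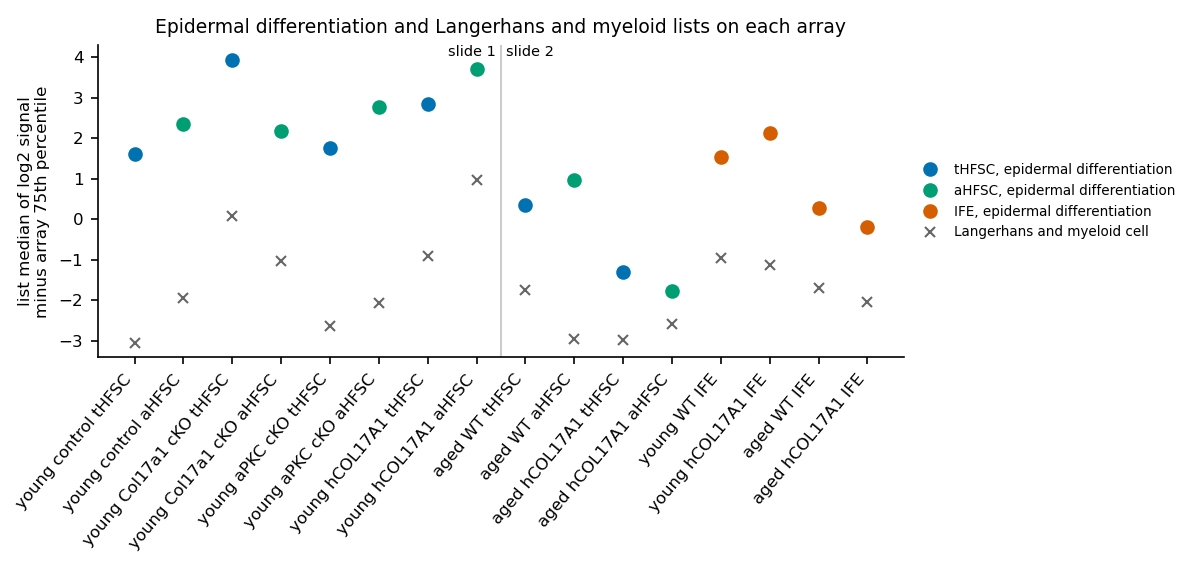
List medians of log2 signal minus the 75th percentile of the array (y axis) on each of the 16 arrays (x axis), 1 point per array and list: coloured circles for the epidermal differentiation list, crosses for Langerhans and myeloid cell markers. The vertical line parts the slides; the median shift of the differentiation list with age was -2.60 in HFSC and -1.38 in IFE.

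In the aPKC cKO, immediate early genes were higher (18 of 20 positive, median 0.58, adjusted p = 0.01, or adjusted p = 0.69 with an estimated correlation). Fos stood at 1.43 ± 0.67 and Fosb at 1.52 ± 0.80. The control arrays, which both knockout comparisons and the transgene comparison share, had the lowest medians of this list among young HFSC arrays (2.06 and 2.08, against 2.62 to 3.89). Upper follicle genes were higher too (10 of 12, median 0.45, adjusted p = 0.0238, or adjusted p = 0.644), a call lost in 7 of 17 alternatives. Cst6 stood at 1.35 ± 0.42 and Gata6 at 1.45 ± 0.62. Cell cycle genes were lower for 28 of 40 members (median -0.39, -0.05 in tHFSC and -0.67 in aHFSC, adjusted p = 0.012, or adjusted p = 0.692). Rrm1 stood at -1.18 ± 0.42 and Uhrf1 at -1.04 ± 0.43. Without the aPKC cKO aHFSC array the median was -0.11 and the test turned to the other direction. limma called 0 genes (1087 of 31545 at an unadjusted p under 0.05, again a smaller share than chance alone gives). Within slide 1 that number was 1720 and without the arrays that stand apart 1709, again larger shares than 0.05. Prorp (1.83 ± 0.26), Snap91 (at least 3.69-fold higher) and the kinesin gene Kifc3 (2.42 ± 0.38) and, lower, P2ry6 (at least 9.12-fold, adjusted p = 0.388), the phosphodiesterase gene Pde8b (-2.10 ± 0.31) and L1td1 (at least 9.68-fold) had the smallest p-values among genes with an official symbol, without passing. Col17a1 (0.14 ± 0.21), Cd34 (-0.38 ± 1.41), Itga6 (-0.10 ± 0.21) and Ly6a (0.29 ± 0.62) had an adjusted p of 1. Leaving out the control aHFSC array gave 1 called gene.

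Tested directly against each other, without the shared control, the Col17a1 cKO exceeded the aPKC cKO in the unfolded protein and integrated stress response list (14 of 15 positive, median 0.38, adjusted p = 0.00133, or adjusted p = 0.472 with an estimated correlation). Ddit3 stood at 1.04 ± 0.62 and Trib3 at 2.09 ± 1.33. It also exceeded it in the wound and stress list (15 of 19, 0.70, 0.39 with normexp, adjusted p = 0.00337, or adjusted p = 0.301). Areg stood at 2.01 ± 0.79 and Ereg at 2.46 ± 1.08. Epidermal differentiation (22 of 28, 0.51, adjusted p = 0.00337, or adjusted p = 0.69, 1.61 in tHFSC and -0.53 in aHFSC) included Dsg1a at 1.47 ± 0.65. Cell cycle (27 of 40, 0.22, adjusted p = 0.0129, or adjusted p = 0.692, -0.14 in tHFSC and 0.81 in aHFSC) included Rrm1 at 1.09 ± 0.42. The differentiation test turned without either tHFSC array of the knockouts (-0.22 and -0.12), and the cell cycle test without the aPKC cKO aHFSC array (-0.01). No gene was called (1349 of 31545 at an unadjusted p under 0.05, limma, a smaller share than chance alone gives). Within slide 1 that number was 1769 and without the arrays that stand apart 1916, here too larger shares than 0.05. The smallest p-values were those of Aif1l (3.33 ± 0.49), Pde8b (2.08 ± 0.31) and Adamts14 (1.97 ± 0.31) and, lower, Snap91 (at least 3.97-fold), Mlc1 (-2.32 ± 0.40) and Dnd1 (-1.56 ± 0.28), with adjusted p from 0.823 to 0.919. Prkci stood 0.83 ± 0.30 higher in the Col17a1 cKO and Ly6a 1.88 ± 0.62, both with an adjusted p of 1. Without the Col17a1 cKO tHFSC array 2 genes passed.

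Whether the knockouts resemble each other or aging was examined across 31074 genes, which are not independent replicates. The effects of the knockouts correlated with r = 0.49, but unchanged arrays measured against the same control arrays gave r = 0.50 in simulation (covariance 0.244 against 0.233). Taking each knockout from a different cell state, with no array shared, gave r = 0.004 and 0.014. The Col17a1 cKO and age effects correlated with r = 0.14 against 0.35 simulated (covariance 0.0703 against 0.117), and with -0.10 and 0.009 where no array was shared. For the aPKC cKO and age the values were 0.17 against 0.35 simulated (covariance 0.0837 against 0.116), and -0.04 and -0.02 without shared arrays.

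**Figure D4:**
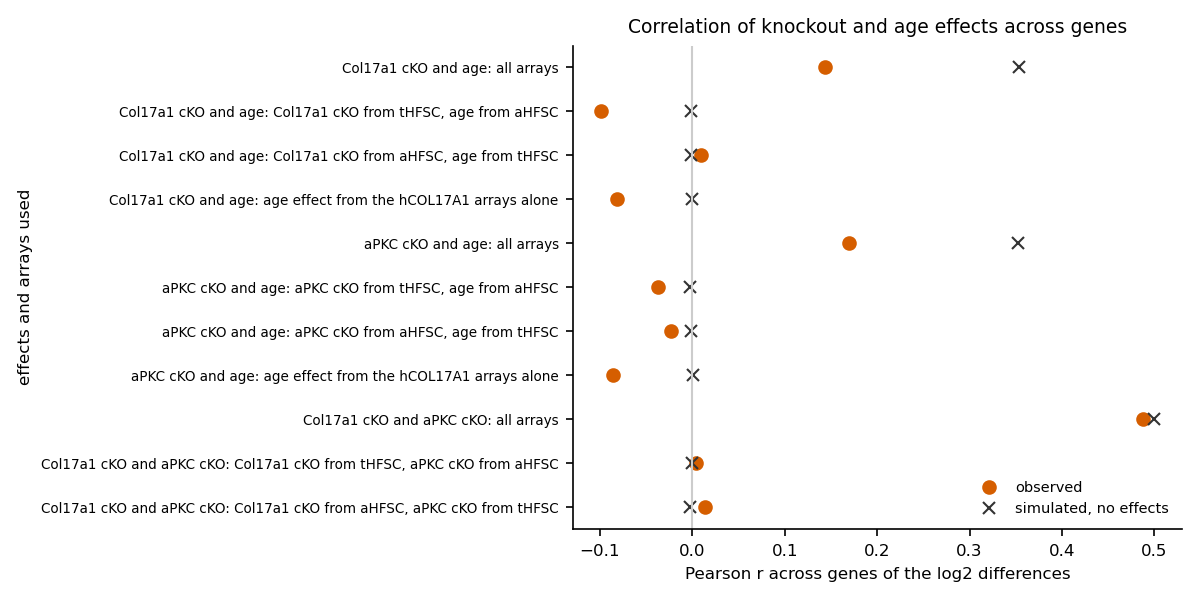
Pearson r across 31074 genes (x axis) between the log2 differences of knockout and age comparisons (y axis: effects and arrays used). Circles are observed values and crosses the mean of 20 simulations of unchanged arrays with the same sharing of controls; with all arrays the simulated value exceeds the observed one in each of the 3 comparisons.

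Aged HFSC were compared with young HFSC over both genotypes and cell states, 4 arrays each. Aged HFSC had lower signals of epidermal differentiation genes: 25 of 28 list members were lower, 1 of them past the threshold over all genes and 21 adjusted over the list alone (median -2.60, against -0.10 for all genes, adjusted p = 6.73e-19, or adjusted p = 0.472 with an estimated correlation). Krtdap fell (-2.68 ± 0.29, adjusted p = 0.0329), and Krt1 (-4.05 ± 0.58, adjusted p = 0.058), Dsg1a (-3.08 ± 0.46, adjusted p = 0.062) and Hrnr (-6.03 ± 0.92, adjusted p = 0.067) lay just outside the threshold. The list median was -0.50 in WT tHFSC, -1.68 in WT aHFSC, -2.98 in hCOL17A1 tHFSC and -5.10 in hCOL17A1 aHFSC. The hCOL17A1 pairs are those in which no label mentions RU486; the aged hCOL17A1 arrays are those with fewer probes above background, and without them the median was -1.02. All young HFSC arrays were on slide 1 and all aged ones on slide 2, so no value with slide as a block exists.

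Other genes past the threshold were the ectonucleotidase gene Entpd3 (at least 7.24-fold higher in aged over both genotypes, but well above background only on the 2 aged hCOL17A1 arrays of the 8, so no bound holds for WT), the urea transporter gene Slc14a1 (3.41 ± 0.36), Smyd4 (2.41 ± 0.24) and the palmitoyltransferase gene Zdhhc1 (2.13 ± 0.24), the last 3 higher in 4 of 4 pairs. Lower in 4 of 4 were Elovl4, which makes very long chain fatty acids of the skin barrier (-3.59 ± 0.32, adjusted p = 0.027), Eva1c (-3.46 ± 0.38) and Aif1l, which was well above background on 1 of 4 aged arrays and has no exact difference. The mean difference for Smyd4 was 0.77 in WT and 4.04 in hCOL17A1 pairs, and for Zdhhc1 0.65 and 3.61. It was most uneven for Entpd3 (1.27 and 6.51) and Aif1l (-0.40 and -6.06), values that are partly measured against background. Eva1c (-3.02 and -3.90) and Krtdap (-1.95 and -3.42) were closer. Slc14a1 stood at 2.34 in WT and 4.47 in hCOL17A1 pairs, and Elovl4 at -2.17 and -5.00. Upper follicle genes were lower (10 of 12, median -0.63, adjusted p = 0.00626, or adjusted p = 0.644), with Cst6 (-1.84 ± 0.30, adjusted p = 0.0756) and the sort gene Ly6a (-2.66 ± 0.44, adjusted p = 0.0806). Wound and stress genes (14 of 19, -0.83, adjusted p = 0.0283, or adjusted p = 0.472) included Ereg (adjusted p = 0.0869, well above background on 1 of 4 aged arrays) and Stfa1 (-4.60 ± 0.94, adjusted p = 0.127, on 2 of 4). Adjusted over the list alone, 2 upper follicle and 4 wound and stress genes were lower, as were 1 cell cycle gene and 3 erythroid markers. Cell cycle genes (32 of 40, -0.64, adjusted p = 0.00309, or adjusted p = 0.69) included Kif11 (-2.68 ± 0.56, adjusted p = 0.133) and Ccna2 (-2.32 ± 0.58, adjusted p = 0.19). With normexp the wound and stress median was -0.37 and the cell cycle median -0.29. These calls were lost in 7 and 4 of 20 alternatives, where the wound and stress median reached -0.16.

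Cholesterol synthesis genes were lower in aged HFSC in 13 of 15 members (-0.64, adjusted p = 0.0184, or adjusted p = 0.644), with Sqle at -1.49 ± 0.37. So were the 4 erythroid markers (-1.31, adjusted p = 0.00404, or adjusted p = 0.602). With normexp the cholesterol synthesis and erythroid medians were -0.34 and -0.28, and the calls were lost in 4 and 3 of 20 alternatives. The globin genes were Hba-a1 (-3.71 ± 0.52, adjusted p = 0.058) and Hbb-b1 (adjusted p = 0.158, not well above background on either aged hCOL17A1 array). Ribosomal protein genes were higher (23 of 24, 0.34, adjusted p = 9.26e-08, or adjusted p = 0.644), but their median was 0.14 with quantile normalization and 0.052 without the aged hCOL17A1 arrays (adjusted p = 0.986). Bulge genes (0.34, adjusted p = 0.00297, or adjusted p = 0.444), BMP and TGF-beta genes (0.32, adjusted p = 0.0464, or adjusted p = 0.472) and oxidative phosphorylation genes (0.17, adjusted p = 0.0275, or adjusted p = 0.841) were higher over both genotypes, but their medians were -0.20, -0.03 and -0.20 without the aged hCOL17A1 arrays, and the calls were lost or turned in 3, 13 and 8 of 20 alternatives. Col17a1 differed by 0.30 ± 0.15 (adjusted p = 0.463, -0.06 in WT pairs and 0.65 in hCOL17A1 pairs), Prkci by 0.55 ± 0.21 (adjusted p = 0.359), Prkcz by -1.29 ± 0.66, Cd34 by 0.34 ± 1.0 and Itga6 by -0.31 ± 0.15. In all 10 genes passed, 5 higher and 5 lower. Of the 8 arrays left out in turn, the count was 0 without young control tHFSC or aged WT tHFSC, 1 without young control aHFSC or young hCOL17A1 aHFSC, 2 without aged WT aHFSC, 3 without young hCOL17A1 tHFSC and 60 without aged hCOL17A1 tHFSC. It was 0 without the 2 arrays that stand apart and 1 without both aged hCOL17A1 HFSC arrays.

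The hCOL17A1 transgene was compared with young control and aged WT HFSC, and the interaction asks whether aging differs with the transgene. Young control mice are labelled with RU486 and hCOL17A1 mice are not, so in the young pairs the transgene cannot be told apart from that treatment. Immediate early genes were higher in transgenic HFSC (18 of 20, median 0.76, adjusted p = 2.13e-07, or adjusted p = 0.644 with an estimated correlation). The shift was 1.39 and 0.96 in the young tHFSC and aHFSC pairs, measured against the low control arrays, and -0.01 and 1.02 in the aged ones. The median was 0.25 without the aged hCOL17A1 aHFSC array (adjusted p = 0.0681). Fos stood at 1.58 ± 0.47 and Dusp1 at 1.15 ± 0.36. Cell cycle genes were lower (35 of 40, -0.57, adjusted p = 0.00199, or adjusted p = 0.69). That call was lost in 4 of 22 alternatives, with medians from -0.86 to -0.33. Bub1 stood at -2.02 ± 0.52 and Ccna2 at -1.98 ± 0.58. A ribosomal protein shift of 0.11 (adjusted p = 0.000291, or adjusted p = 0.69) had the opposite sign in the young arrays (-0.15) and with quantile normalization (-0.01). No gene passed (limma; 2523 at an unadjusted p under 0.05). The smallest p-values were those of the sphingosine kinase gene Sphk1 (2.74 ± 0.37), Prorp (1.35 ± 0.18) and the tight junction gene Ocln (1.67 ± 0.25), and, lower, Ccdc15 (-3.25 ± 0.34, adjusted p = 0.195), Armcx6 (at least 6.05-fold) and Zfp324 (at least 1.75-fold). Mouse Col17a1 differed by 0.36 ± 0.15 (adjusted p = 0.607). Without the young control aHFSC array 2 genes passed, and without young hCOL17A1 aHFSC 1.

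The interaction was positive for 21 of 21 bulge stem cell genes: their change with age was more positive in transgenic than in WT HFSC (median difference of differences 1.29, against -0.24 for all genes, 1.36 in tHFSC and 1.41 in aHFSC, adjusted p = 8.36e-09, or adjusted p = 0.146 with an estimated correlation). Wif1 stood at 3.28 ± 0.66 and Sox9 at 1.47 ± 0.35. Hemidesmosome and basement membrane genes went the same way (16 of 21, 0.70, adjusted p = 0.000701, or adjusted p = 0.472). Itgb1 stood at 1.59 ± 0.55 and Col17a1 at 0.71 ± 0.30. So did BMP and TGF-beta genes (15 of 20, 1.17, adjusted p = 0.00133, or adjusted p = 0.264). Smad9 had a positive difference. Positive as well were oxidative phosphorylation (25 of 26, 0.49, adjusted p = 3.62e-05, or adjusted p = 0.69) and ribosomal protein genes (23 of 24, 0.54, adjusted p = 9.26e-08, or adjusted p = 0.644). With quantile normalization these 2 medians were 0.22 and 0.27, and without the aged hCOL17A1 aHFSC array oxidative phosphorylation did not pass (0.24, adjusted p = 0.111). The opposite sign was found for epidermal differentiation (25 of 28, -3.04, adjusted p = 2.04e-07, or adjusted p = 0.644). Flg stood at -7.74 ± 1.57 and Lce1a1 was negative. Langerhans and myeloid markers were negative (11 of 11, -1.71, adjusted p = 0.0238, or adjusted p = 0.644). H2-Ab1 stood at -4.55 ± 1.15. T cell markers were negative (7 of 8, -1.39, adjusted p = 0.0275, or adjusted p = 0.644). With normexp the differentiation median was -1.58, the myeloid one -1.15 and the T cell one -0.65, and with quantile normalization the hemidesmosome one was 0.45. The T cell call was lost in 5 and the myeloid call in 4 of 19 alternatives. Cd3d was among the negative T cell markers. No list member passed over all genes, while adjusted over the list alone 3 bulge genes and 1 BMP and TGF-beta gene were higher and 8 epidermal differentiation genes and 1 myeloid marker lower. limma called 0 genes (3347 at an unadjusted p under 0.05), with B4gat1 (3.47 ± 0.49), Smyd4 (3.27 ± 0.48) and Cstf3 positive and Igf2bp3, Aif1l and the Wnt inhibitor gene Apcdd1 negative, at an adjusted p of 0.218 each. Smad9, Lce1a1, Cd3d, Cstf3, Igf2bp3, Aif1l and Apcdd1 were not well above background on either HFSC array of at least 1 of the 4 conditions, so only their direction is given. Without young control aHFSC or without young hCOL17A1 aHFSC 1 gene passed. This contrast rests on the arrays with the fewest probes above background. Its WT side sets aged WT against young control, and of the 4 conditions only young control is labelled with RU486. The interaction therefore cannot be told apart from that treatment.

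In IFE, aged arrays had lower epidermal differentiation signals as well, here with all arrays on slide 2: 25 of 28 members were lower (median -1.38, against -0.11 for all genes, -0.89 in WT and -2.01 in hCOL17A1, adjusted p = 1.11e-06, or adjusted p = 0.644 with an estimated correlation). Calml3 stood at -2.46 ± 0.51 and Dmkn at -1.37 ± 0.36. Wound and stress genes (14 of 19, -0.36, adjusted p = 0.0223, or adjusted p = 0.472) included S100a9, not well above background on either aged IFE array, and Stfa1 at -5.76 ± 1.34. Cholesterol synthesis genes (10 of 15, -1.04, adjusted p = 0.0309, or adjusted p = 0.644, a call lost in 9 of 17 alternatives) included Sqle at -2.38 ± 0.53 and Fdps at -2.05 ± 0.62. Adjusted over the list alone, 1 differentiation, 3 wound and stress and 1 cholesterol synthesis gene were lower. Oxidative phosphorylation shifted by -0.53 (adjusted p = 0.00377, or adjusted p = 0.735), but by -0.27 with quantile normalization and by 0.08 in the WT pair. limma called 0 genes for age in IFE (1991 at an unadjusted p under 0.05): Sall2 (at least 4.32-fold), the gut peptide gene Pyy (2.48 ± 0.43) and Ly6g6d (at least 5.60-fold) (higher) and the T cell receptor component Cd3g (-4.42 ± 0.68, adjusted p = 0.677), Crispld2 (-1.87 ± 0.29) and Arhgap24 (-4.40 ± 0.69) (lower) had the smallest p-values among genes with an official symbol. With a single young or aged array per genotype the counts moved: 236 without young WT IFE, 238 without aged WT IFE, and 1 without either hCOL17A1 array. A group left with 1 array is assumed to vary like the other groups.

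For the transgene in IFE no list passed and limma called 0 genes (1710 at an unadjusted p under 0.05). The ceramide synthase gene Cers5 (3.15 ± 0.38, adjusted p = 0.612), Mug2 (at least 2.32-fold higher), Bcan (at least 4.06-fold higher), the taurine transporter gene Slc6a6 (-0.90 ± 0.17), Ass1 (-1.28 ± 0.31) and Myl1 (at least 1.77-fold lower) had the smallest p-values. Without either aged IFE array 90 genes passed.

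Finally, the change between cell states was compared between ages, 2 aged pairs against 4 young pairs. The aHFSC-minus-tHFSC shift of immediate early genes was 1.21 and 1.64 in the aged pairs and from -0.77 to 0.34 in the young ones, where 2 of 4 were negative (difference positive for 17 of 20, median 1.52, adjusted p = 3.4e-09, or adjusted p = 0.472 with an estimated correlation), 1.35 for the WT and 1.58 for the hCOL17A1 pair. Jun stood at 1.65 ± 0.41 and Zfp36 at 2.27 ± 0.60. Cholesterol synthesis genes had a more positive shift in aged mice (10 of 15, 0.57, adjusted p = 0.0238, or adjusted p = 0.644). Cyp51 stood at 2.31 ± 0.61. Epidermal differentiation genes had a more negative one (22 of 28, -0.91, -0.60 with normexp, adjusted p = 0.00373, or adjusted p = 0.69). These 2 calls were lost in 9 and 8 of 24 alternatives. Sprr1b was negative and well above background on 1 of 4 aged HFSC arrays. Ribosomal protein genes differed by 0.28 (adjusted p = 0.00133, or adjusted p = 0.713), but by 0.19 with quantile normalization and by -0.08 for the WT pair. No gene passed in limma (1959 at an unadjusted p under 0.05); Sox4 (3.21 ± 0.41), Ccser1 (4.06 ± 0.62), the connexin gene Gjb6 (4.26 ± 0.66), Pfkfb4 (negative), Magi3 (-5.03 ± 0.67) and Rnf32 (-3.21 ± 0.45) had the smallest p-values, each with an adjusted p of 0.494. Pfkfb4 was not well above background on either aged aHFSC array, so its difference is not exact. Magi3, Rnf32 and Gjb6 each missed that level on 1 aged array. Adjusted over the list alone, 3 immediate early genes were higher and 1 differentiation gene lower. The cell cycle list, which rose with the change of state, was not among those that differed between ages.

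**Figure D5:**
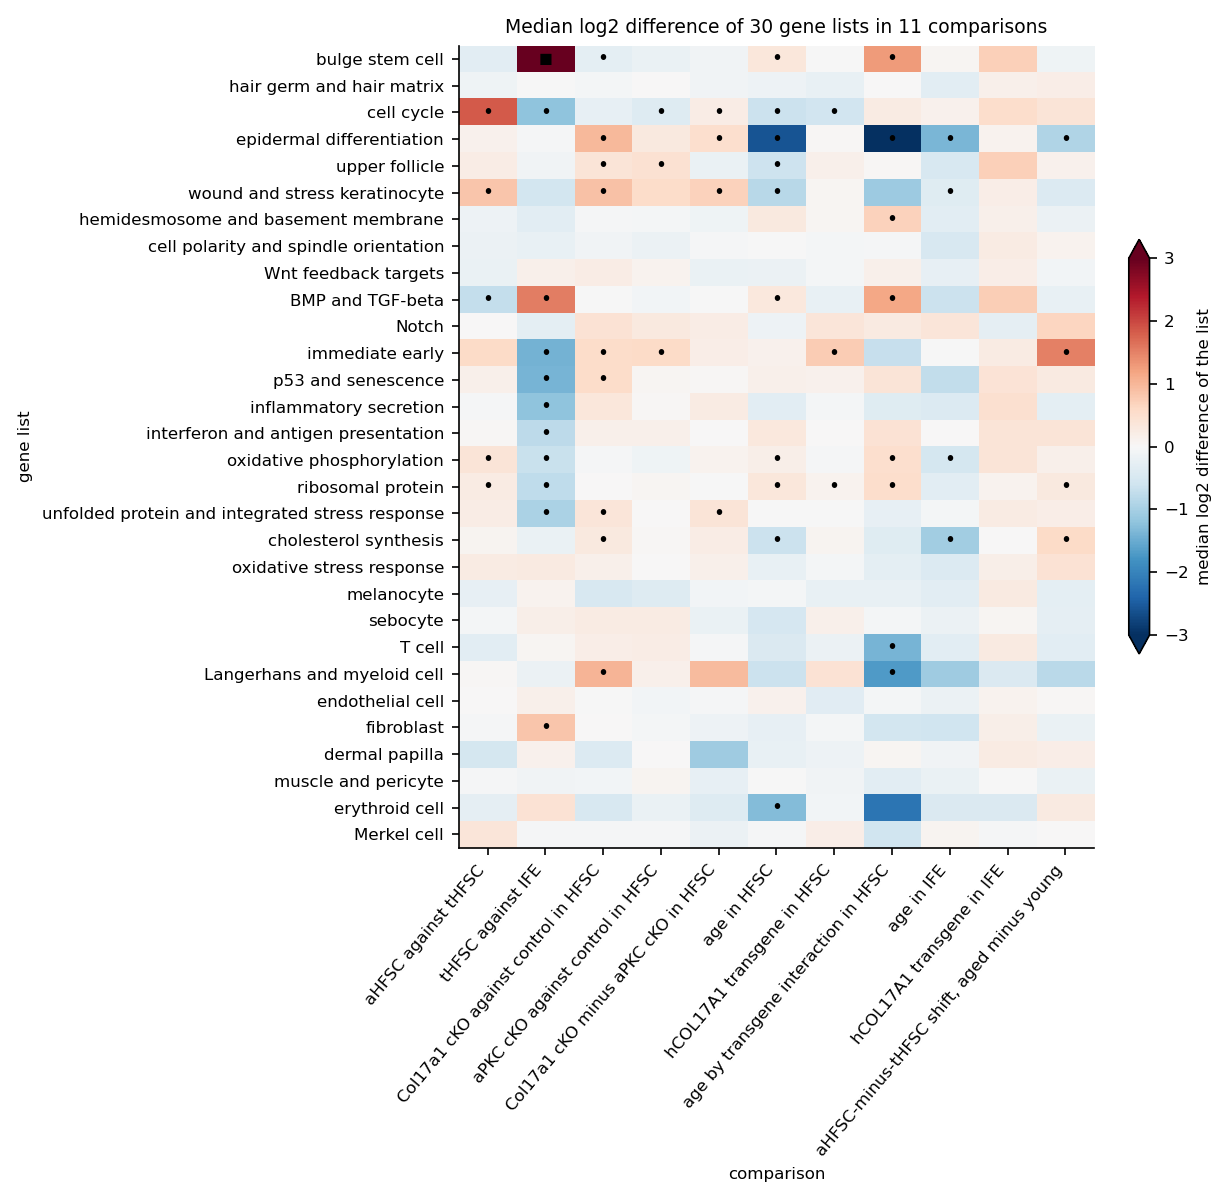
Median log2 difference (colour, truncated at -3 and 3) of 30 gene lists (y axis) in 11 comparisons (x axis). A dot marks an adjusted p under 0.05 with camera's preset correlation and a square one that also passed with an estimated correlation, which is the bulge stem cell list in tHFSC against IFE.

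Genes of cell polarity and spindle orientation, the group closest to the study's question on division, passed as a list in none of the 11 comparisons: the medians lay between -0.47 (age in IFE, adjusted p = 0.131) and 0.24 (transgene in IFE, adjusted p = 0.79), with -0.11 in the Col17a1 cKO (adjusted p = 0.926) and -0.17 in the aPKC cKO (adjusted p = 0.436). Hair germ and hair matrix, Wnt feedback target, Notch, oxidative stress response, melanocyte, sebocyte, endothelial, dermal papilla, muscle and pericyte, and Merkel cell lists also passed in none; the smallest adjusted p among these 11 lists was 0.0658, for Notch.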

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

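The explanations below were tested after the patterns were seen, except the regrouping over all arrays and the age effect of genes higher in IFE, which were written down before. Flagged here are gene lists whose effect differs between groups by a test of the difference itself, with camera's preset correlation. All 16 lose the call with an estimated correlation.

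The Col17a1 cKO differed from the aPKC cKO in the cell cycle (0.22), epidermal differentiation (0.51), wound and stress keratinocyte (0.70) and unfolded protein and integrated stress response lists (0.38). The change with age differed between hCOL17A1 and WT HFSC in the bulge stem cell (1.29), epidermal differentiation (-3.04), hemidesmosome and basement membrane (0.70), BMP and TGF-beta (1.17), oxidative phosphorylation (0.49), ribosomal protein (0.54), T cell (-1.39) and Langerhans and myeloid cell lists (-1.71). The young side of WT here is the control labelled with RU486, so this difference cannot be told apart from that treatment. The aHFSC-minus-tHFSC shift differed between aged and young mice in the epidermal differentiation (-0.91), immediate early (1.52), ribosomal protein (0.28) and cholesterol synthesis lists (0.57).

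Epidermal differentiation genes were lower in aged HFSC, a call lost with an estimated correlation (adjusted p = 0.472). Weak hybridisation of the aged hCOL17A1 arrays is excluded as the whole cause by the tested limit, since the list median was -1.02 without them. Less IFE RNA in the aged sorts was examined by shares. Over the 4 pairs the lost signal needs a median of 13.7% to 139% IFE RNA in the young sort. Genes far brighter in IFE allow 0.84% to 9.81%. Those 8 to 27 genes were chosen as far dimmer on the other HFSC arrays, most of them young, so their low share is partly set by that choice. In the hCOL17A1 pairs the IFE reference was the young hCOL17A1 IFE array, which stands apart and may hold HFSC RNA. Within these limits the shares argue against this cause for the list as a whole without excluding it. The 1357 genes called higher in IFE had a median age effect of -0.058, but they went both ways and decide nothing alone. A slide difference cannot be told apart in HFSC, while in IFE, with all arrays on slide 2, the list shifted by -1.38. Langerhans and myeloid (median -0.65) and T cell markers (-0.42) were lower too without passing, so fewer other cells in the sort, fewer differentiating cells despite the ITGA6-high gate, and lower expression with age, the biological explanation, stay open and were not separated from the slide.

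Some bulge genes were raised on the young hCOL17A1 IFE array. Of 26 genes far higher in tHFSC than in the other IFE arrays, 17 (65.4%) were over 2-fold higher on it. On the other IFE arrays, measured the same way, the shares were 4.17%, 19.1% and 17.4%. The reference for those arrays includes the young hCOL17A1 IFE array, so their shares are partly lowered by construction, also for the dim genes below. HFSC RNA carried into this sort may account for the raised genes, at a median of 4.02% of the tHFSC level, but not at the same share for all genes. Dab2, Pdzrn4 and Angptl7, with tHFSC means of 4.705, 3.063 and 3.495, were not well above background on this array, while Cd34, Lgr5 and Tbx1 were raised. All of these were named for large differences from IFE, a choice that favours genes dim on this array. Carry-over is therefore neither shown nor excluded. Generally raised dim signals cannot be excluded, since 20.5% of dim genes were over 2-fold higher on this array, against 8.03%, 4.39% and 13.3%. A first form of this test held too few genes to decide and was replaced after it had been seen, and a transgene effect on these genes was not tested separately.

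Epidermal differentiation genes were higher in the Col17a1 cKO, a call lost with an estimated correlation (adjusted p = 0.644), by a list median of 1.82 in the tHFSC pair and -0.052 in the aHFSC pair. Across the 12 HFSC arrays the list's median followed that of Langerhans and myeloid markers (r = 0.70, permutation p = 0.0112, adjusted over 4 relations 0.0223), also without the Col17a1 cKO tHFSC array (0.638, permutation p = 0.0341) and within slide 1 (0.89). For T cell markers r was 0.755, but 0.406 within slide 1 and 0.399 without both aged hCOL17A1 arrays, and for upper follicle genes 0.64, but 0.377 within slide 1. Bulge genes did not pass (-0.55, permutation p = 0.0608), but stood at -0.658 (permutation p = 0.0274) without the Col17a1 cKO tHFSC array. The permutations treat the 12 arrays as exchangeable, though they form pairs by condition and age lies with slide, so these p-values may be too small. RNA of other skin cells in the sort cannot be told apart from the group, since the 2 kinds of marker part within slide 1 and the gate for CD34-high, ITGA6-high and Sca1-negative cells selects against them. A change in 1 cell state stays open too, with 1 array per state and group, and a biological effect of Col17a1 loss was not tested separately.

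Regrouping the arrays asks whether chance can be excluded. For aHFSC against tHFSC 1 of 100 splits drawn from 462 gave as many genes, the real one with 170, and the highest other gave 2. Those splits ignore the pairs by condition, so the states were also swapped within conditions: 1 of 32 swaps gave as many, the real one, and the highest other gave 9. In every other split the real shift adds to the residual spread, so low counts there are partly set in advance. The real grouping gave the most genes both ways, but these counts alone do not exclude chance. For tHFSC against IFE, in an unpaired fit, 1 of 35 splits gave as many, the real one with 1398. The highest other gave 0, with the same limit. For age in HFSC and for the transgene in HFSC the unpaired fit gives 0 genes for the real grouping, so 35 of 35 splits reached it by construction and the count decides nothing. The 10 genes reported for age come from the fit with pairs. The highest other split, which follows cell state, gave 6 in both.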

How the results depend on the processing

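Over all alternatives, 164 counts of called genes stayed within 1.5 times the reported one and 53 moved, but 134 of the 164 are 0 against a reported 0, in 8 of 11 comparisons. Of reported counts above 0, 30 stayed and 37 moved. Values of named genes kept their direction and side of the threshold in 3533 cases, weakened in 642, strengthened in 18 and reversed in 3 (of the 3533, 2207 were of genes not past the threshold to begin with), and list tests did so in 1041, 219, 0 and 16. Unless the construction shows it, the cause was not tested. No paired analysis by replicate number was possible because all arrays have number 1, while the fit pairs tHFSC and aHFSC by condition. Age in HFSC has no value with slide as a block, and the interaction and the difference in state shift have none within a slide. Signal over background limits the dim probes, most on the aged hCOL17A1 HFSC arrays. Only probes in all 16 scanner files, leaving out the arrays that stand apart, leaving out both aged hCOL17A1 HFSC arrays, and age from hCOL17A1 arrays alone were added after seeing the data.

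For aHFSC against tHFSC 304 genes passed with unpaired groups, 14 without a trend, 0 within slide 1 and 0 within slide 2 (fewer arrays), 111 without the arrays that stand apart, 79 without both aged hCOL17A1 HFSC arrays, and 0 to 95 leaving out 1 array. For tHFSC against IFE 960 passed with only the arrays of the comparison, 83 within slide 2, 143 with slide as a block and 830 to 2231 leaving out 1 array. The Col17a1 cKO gave 1 without a trend and 0 to 2 leaving out 1 array, the aPKC cKO 0 to 1, and the difference of the knockouts 0 to 2. Age in HFSC gave 5 with only probes above background on all 16 arrays, 0 unpaired, 0 without the arrays that stand apart, 1 without both aged hCOL17A1 HFSC arrays and 0 to 60 leaving out 1. The transgene in HFSC gave 0 to 2, the age by transgene interaction 0 to 1, age in IFE 5 with only its arrays and 1 to 238 leaving out 1, and the transgene in IFE 0 to 90.

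Reversed without both aged hCOL17A1 HFSC arrays were, for age in HFSC, Col17a1 (-0.062) and the bulge stem cell (-0.20), BMP and TGF-beta (-0.035) and oxidative phosphorylation (-0.20) lists, for the transgene in HFSC the ribosomal protein list (-0.15, also -0.15 within slide 1), and for the aged minus young state shift the ribosomal protein list (-0.083, and -0.083 without the arrays that stand apart). The oxidative phosphorylation list for age in IFE gave 0.084 without the arrays that stand apart. Adamts14 in the Col17a1 cKO minus aPKC cKO difference gave -0.37 with only probes in all 16 files, where another probe stands for the gene. Leaving out 1 array reversed 6 results, which ranged from -1.08 to 0.22 for Prkcz in the aPKC cKO, from -0.75 to -0.11 for its cell cycle list (where the test direction turned), from -0.011 to 0.81 for the cell cycle and from -0.22 to 1.26 for the epidermal differentiation list in the knockout difference, from -1.21 to 0.084 for oxidative phosphorylation with age in IFE, and from -0.083 to 0.56 for ribosomal protein genes in the state shift. Correlations reversed for the Col17a1 cKO and age (-0.099 from different states, -0.082 with hCOL17A1 arrays alone) and for the aPKC cKO and age (-0.037, -0.023 and -0.086).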

Other observations

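The 2 genes named in both knockout comparisons for their smallest p-values, P2ry6 and Prorp, were highest and lowest, respectively, on the control arrays, which both comparisons share. The nucleotide receptor gene P2ry6 stood at -2.05 and -2.10 on the young control arrays and between -5.97 and -4.97 on the other 14. Prorp, a mitochondrial RNase P subunit gene, stood at 0.81 and 1.79 on the control arrays and from 1.89 to 4.12 on the others. Over the alternatives the Prorp difference fell to 0.36 in the Col17a1 cKO, 0.17 in the aPKC cKO and 0.14 for the transgene in HFSC. That of P2ry6 reached -0.89 in the Col17a1 cKO and -0.81 in the aPKC cKO, smaller than its bounds. These genes were examined in this way after their values were seen, and no test was made.

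On the young hCOL17A1 IFE array some other follicle genes stood apart too. Lgr5 stood at -0.91 against -6.44, -6.38 and -6.29 on the other IFE arrays, and Tbx1 at -0.42 against -3.99, -4.20 and -3.62. Not all did: Wif1 and Tcf7l1 were not well above background on any IFE array. Runx1 and Krt6a were well above background on the other IFE arrays but not on this one. Across genes, the age effects in HFSC and IFE, which share no array, correlated with r = 0.10, against 0 in simulation, but with a Spearman correlation of 0.027, and 51.3% of genes had the same sign.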
